A study of Trametes gibbosa with 15 samples.

How the data were processed

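Poly-A RNA from mycelium was sequenced as 15 libraries in 5 groups of 3, per the labels' protocols. The submitters' processing notes list HISAT2, StringTie, DESeq 1.10.1 and DESeq2 without saying what each did, and the reference build and annotation are not given in the sources used here. The authors deposited a table of estimated counts per gene and library, a table of FPKM values, and an annotation of newly assembled loci whose source column names StringTie. Per the file headers, the count table also has a gene length, which equals the summed length of all transcripts for 847 of 847 newly assembled loci. The deposited counts are whole numbers. For newly assembled loci with a single transcript and 100 or more counts (16 to 38 per library), they lay within 2% of FPKM times length over a constant of the library. Of 4459 counts from 1 to 50 in the 509 loci with a single transcript, 99.7% equalled that product rounded up, so counts of such loci are estimates rounded up. Loci with several transcripts and reference genes were not checked in this way, and all counts were used as deposited. The FPKM values deposited by the authors are scaled by transcript length and mapped fragments and were used only for alternatives. Low counts were steady: 50 of 237 genes with all wood counts from 1 to 10 were constant within each library series. Choosing genes by that range itself narrows their counts, and the number expected from sampling under that choice was not computed.

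Columns were matched to samples by title. One count column of day 5 carries no replicate number that matches a title, so it was used as an unnumbered library of that group and placed in the second series, the series of the only day 5 sample left. The FPKM table instead has a column titled as replicate 3 of day 5. In the check above, all 29 loci compared between both columns lay within 2% of the library's constant. Both columns thus hold the same library, which keeps the name unnumbered below. No pair of libraries agreed within sampling noise (chi-square per degree of freedom 108 to 333 within groups). Spearman correlations were 0.958 to 0.975 within groups and 0.925 to 0.941 between control and wood libraries.

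Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passing filterByExpr (11386 of 12885) were scaled by TMM and fitted by robust quasi-likelihood with group and library series as terms over all 15 libraries, leaving 9 residual degrees of freedom. The biological coefficient of variation was 38.8%. The controls are all in the first series and day 11 all in the second, so day 11 against control rests on the series shift estimated from days 3, 5 and 7. That shift passed an adjusted p under 0.05 in 2296 genes (edgeR), and in 306 of them it was 2-fold or more. Calls needed a Benjamini-Hochberg adjusted p under 0.05 and a change of 2-fold or more. Log2 fold changes were fitted with the series term and need not equal the ratio of the printed group means. The SE printed with a log2 fold change is the size of that change divided by the square root of the test's F statistic. It is not a standard error taken from the fit. The designs, alternatives and naming rule were fixed before the data were examined. With no product names, the rule took per comparison the called reference gene and newly assembled locus with the largest log2 fold change in each direction, among those with a mean of 10 CPM or more in a group and no overlap between groups. Lists of ligninolytic, cellulolytic and other genes had been fixed by product keyword, and none could be matched, so only the list of newly assembled loci was tested, with camera (preset correlation 0.01) in limma 3.58.1. Shares of counts were compared by exact permutation.

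The procedure was tested on simulated counts for 11386 genes with 100 genes changed 2-fold and 100 changed 4-fold. For day 3 against control 23% of the 2-fold and 70% of the 4-fold changes were recovered at an adjusted p under 0.05, for day 11 against control 18% and 66%, and for day 11 against day 3 42% and 80%. Alternatives covered DESeq2 1.42.0, other scaling factors, filters, limma on FPKM with pseudocounts of 1 and 0.1, the series term, a replicate block, single library series and leaving out each library. Added after seeing the data were the first series with 1 library per day, thinning of counts, library totals as scaling, and fits without the 100 most abundant genes or without genes that range 100-fold within a group.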

Results

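Gene expression was measured in mycelium of the white-rot fungus Trametes (Lenzites) gibbosa, strain CB-1, a basidiomycete that decays wood. Stationary liquid cultures were grown for 10 days and then either harvested without wood (control) or given 2 g of poplar chips and harvested 3, 5, 7 or 11 days later. Each of the 5 groups had 3 libraries, described in the labels as biological replicates, which gives 15 libraries and 12 of them with wood. The control was harvested when the wood was added, so every wood library also came from an older culture, and no library of equal age without wood was analysed here. Total estimated counts per library lay between 32472274 and 48361622. The libraries fall into 2 series by the codes in their labels. The first series holds the 3 controls and replicate 1 of days 3, 5 and 7 (6 libraries, 32472274 to 35419940 counts), and the second holds the other 9 libraries (40193836 to 48361622 counts). The table lists 12885 genes, of which 12038 carry reference identifiers and 847 are loci newly assembled by the authors. The files used here do not pair these identifiers with gene names or products, so genes are named by identifier and no enzyme family is described.

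The comparison of each wood day with the control asks which genes changed once the fungus grew with wood. At day 3 with wood, 381 genes were higher and 661 lower than in the control, out of 11386 tested. At day 5 the numbers were 422 higher and 716 lower, at day 7 they were 541 and 880, and at day 11 they were 514 and 699. In the mean of the 4 wood days, 477 genes were higher and 770 lower than in the control. The median log2 fold change of the higher genes was 1.33 at days 3, 5 and 7 and 1.44 at day 11, and that of the lower genes was -1.59, -1.53, -1.62 and -1.61. Changes of 4-fold or more were found in 77, 77, 81 and 111 higher genes and in 191, 213, 294 and 239 lower genes at the 4 days. Day 11 is the only wood day that shares no library series with the control. Its larger values among higher genes thus rest on the series shift estimated from days 3, 5 and 7, and were not separated from it. A gene was called at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg) with a change of 2-fold or more.

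These directions are relative to the middle of all genes, and the split between higher and lower depended on that choice. With library totals as the scaling, chosen after seeing the data, 1546 genes were higher and 417 lower in the mean of the wood days, and the median of all genes then lay 0.45 (log2) above the control. With that scaling, the splits at days 3, 5, 7 and 11 were 1077 higher and 382 lower, 1399 and 376, 1830 and 464, and 1863 and 360. The deposited FPKM values, on the log2(FPKM + 1) scale and tested with limma, gave 1064 higher and 381 lower for the mean of the wood days. Upper-quartile factors gave 633 higher and 599 lower at day 11. Without the library series term the counts called at days 3 and 11 were 1225 and 1366, but they shared 815 of the 1042 genes called at day 3 and 794 of the 1213 at day 11. A replicate block beside the series term, fitted without the unnumbered day 5 library, lowered both the higher and the lower count at day 11. Its counts are listed in the section on how results depend on processing.

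**Figure D1:**
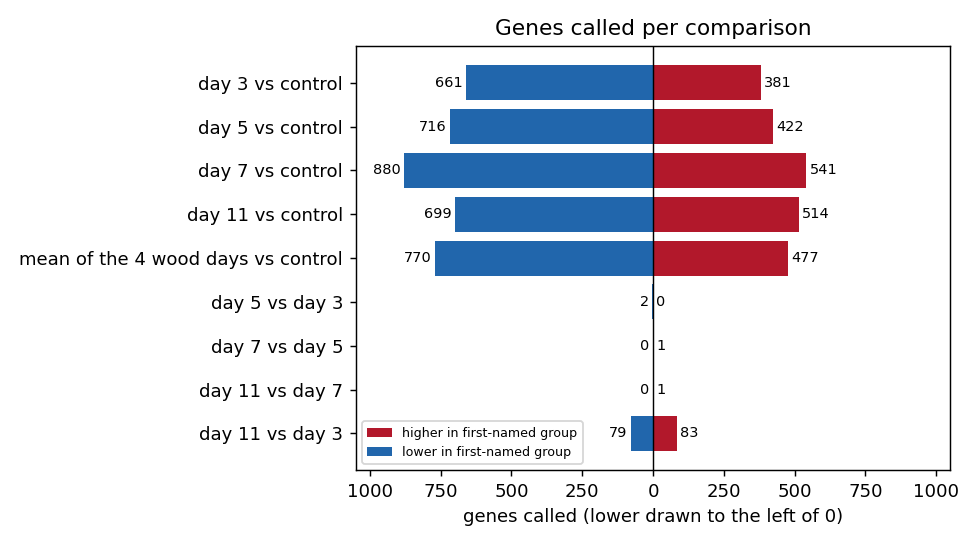
Number of genes called in each comparison (x axis, genes), with genes higher in the first-named group drawn to the right of 0 and genes lower drawn to the left. The comparisons of a wood day with the control hold 1042 to 1421 genes, and those between successive wood days hold 1 or 2.

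Among reference genes, gene_1523 was the top-ranked riser at every wood day. Its control libraries held 2 counts in total, against 13832 counts over the 12 wood libraries, a ratio of 1056 with a 95% counting interval of 292 to 8721 (exact binomial). The mean was 26.0 ± 20.2 CPM (SD, n = 12) with wood, and the fitted log2 fold change was 10.09 (SE 2.14, derived from the F statistic, edgeR adjusted p = 0.0047). Replicate 2 of day 11 stood apart, with 6 counts where the other 2 libraries of that day held 1886 and 1980, so that the gene ranged over 100-fold within that group. The gene was higher than all 3 controls in 12 of 12 wood libraries, which the naming rule required for the mean of the wood days.

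The top-ranked falling reference gene in the mean of the wood days was gene_2985, which fell from 43.9 ± 8.13 CPM (SD, n = 3) in the control to 0.0989 ± 0.0238 CPM (SD, n = 12) with wood (log2 fold change -8.28, SE 0.21, edgeR adjusted p = 1.1e-09). All 12 wood libraries held 4 or 5 counts, against 955 to 1361 in the controls. Deposited FPKM values were 28.4 to 36.6 in the controls and 0.0920 to 0.174 with wood. Low estimated counts in these files varied little. In 237 genes whose wood counts all lay between 1 and 10, the median ratio of variance to mean was 0.31. Choosing genes by that range lowers the ratio by itself, and the value expected from sampling was not computed. The size of this fold and its SE rest on low counts of uncertain precision, while its direction does not.

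The top-ranked falling genes of days 3, 7 and 11 rested on few control libraries and were also high in single wood libraries. For gene_2487, replicate 2 of day 7 held 4160 counts. For gene_2368, replicate 3 of day 3 held 3176 counts, and for gene_10199, replicate 2 of day 3 held 1231, both above every control. On the scale of CPM + 0.1, with this CPM taken by library totals and without TMM factors, gene_2487 and gene_2368 ranged 100-fold or more within a group. These genes thus varied between libraries with and without wood. For gene_2487 at day 3 (edgeR adjusted p = 0.027), replicate 2 of the control held 5482 of the 5856 control counts, and without it the adjusted p was 0.074. Its mean was 74.2 ± 117 CPM in the control and 0.285 ± 0.119 CPM at day 3 (SD, n = 3), with 37 counts at day 3 and a ratio of 244 (counting interval 177 to 347). The fitted log2 fold change of -13.01 (SE 3.65) exceeds that ratio, and without the series term it was -7.99 with an edgeR adjusted p of 0.067. The call was lost in 6 of the 15 fits that leave out 1 library. For gene_2368 at day 7 (adjusted p = 0.036 in the same test), replicate 3 of the control held 967 of 969 control counts, and without that library the adjusted p was 0.36, the call being lost in 7 of the 15 such fits and, with an adjusted p of 0.0605, without the series term. Its day 7 libraries held 3 counts in total, and the ratio of control to day 7 was 547 (counting interval 187 to 2655). For gene_10199 at day 11, control replicates 1 and 2 held 518 and 352 counts and replicate 3 held 2, with 3 counts over day 11 (ratio 487, counting interval 166 to 2367, edgeR adjusted p = 0.012, and 0.051 without replicate 1 of day 3). These intervals cover counting error only and are nominal at such low counts.

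Newly assembled loci were called less often than reference genes. In the mean of the wood days, 38 of 616 tested loci were called (6.17%), 21 higher and 17 lower, against 11.2% of reference genes (Fisher's exact test across genes, which are not independent replicates, p = 3.6e-05). All 847 loci held only 0.437% to 1.76% of counts per library, and this comparison took no account of abundance. As a list, the loci showed no shift against the other genes (camera adjusted p = 0.55, and adjusted p = 0.70 with an estimated correlation). The fry test, which makes no comparison with other genes, gave an adjusted p of 0.57 for change in 1 direction. For change in either direction the unadjusted fry p was 1.4e-13, so members of the list did change. Trametes_gibbosa_newGene_644, on scaffold 1 from 1019121 to 1023766 on the minus strand with 6 transcripts, rose from 11.9 ± 0.866 CPM (SD, n = 3) to 25.8 ± 8.28 CPM (SD, n = 12), a log2 fold change of 1.61 (SE 0.27, edgeR adjusted p = 0.0011). Trametes_gibbosa_newGene_645, on scaffold 22 from 299655 to 301015 on the minus strand with 2 transcripts, fell from 11.7 ± 1.18 to 3.39 ± 0.875 CPM (log2 fold change -2.01, SE 0.37, edgeR adjusted p = 0.0017). Both were called in the same direction at each of the 4 wood days. The genome build behind these coordinates is not given in the sources used here.

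**Figure D2:**
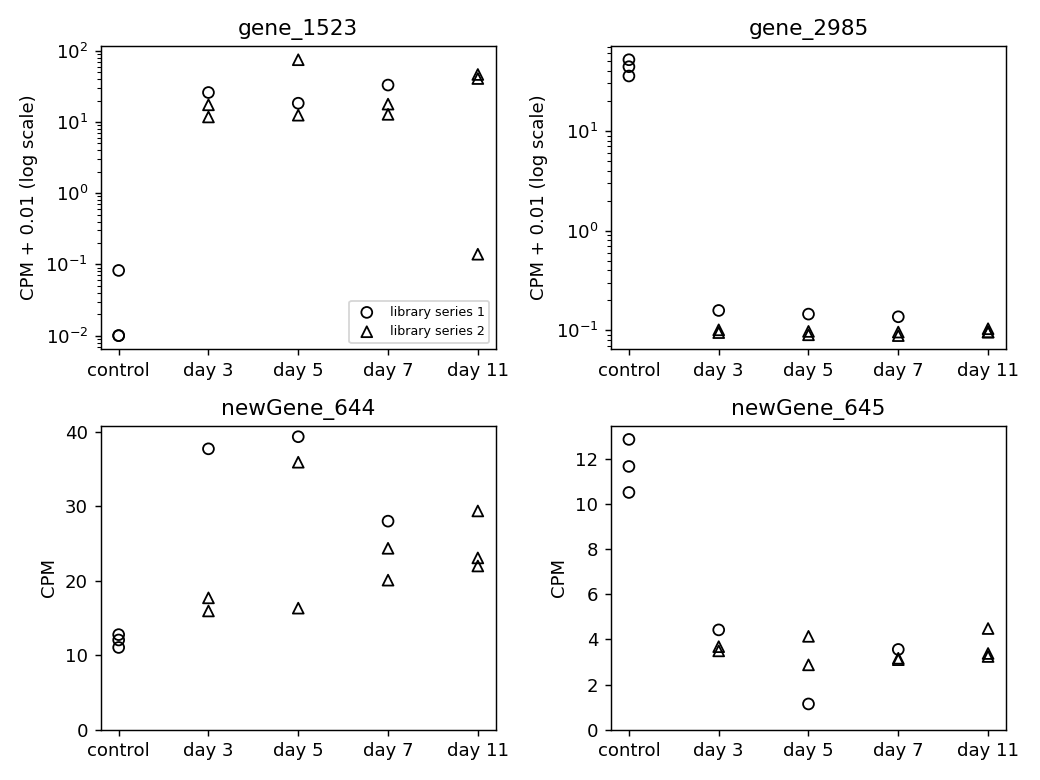
CPM per library (y axis) for gene_1523, gene_2985, newGene_644 and newGene_645 by group (x axis, control or days with wood), circles for the first library series and triangles for the second. The upper panels have log axes of CPM + 0.01 and the lower panels linear axes from 0, and gene_2985 lies near 0.1 CPM in all 12 wood libraries.

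The overlap between days shows how far the same genes were called. Of 1894 genes called on at least 1 day, 206 were higher at all 4 days and 438 lower at all 4, and 0 were higher on 1 day and lower on another in the edgeR test. Days 3 and 11 shared 234 higher and 472 lower genes, where independent lists of those sizes would share 17.2 and 40.6. The 4 comparisons share the 3 control libraries. Unchanged groups simulated against those controls shared 0 calls on average over 20 simulations. Such groups have no true calls to share, so this 0 does not show what sharing the controls adds to the overlap. The simulated fold changes still correlated by 0.67 for days 3 and 11, beside 0.74 observed across genes. The observed covariance was 1.29 and the simulated one 0.45. The 3 controls cannot be divided so that each part keeps 2 libraries, and part of the excess may come from sharing them. The 438 genes lower at all 4 days, chosen on these same libraries, held 23.7% ± 0.540 (SD, n = 3) of control counts and 7.11% to 8.24% in the wood groups.

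The counts were spread over more genes with wood. The 10 most abundant genes of each library held 7.76% ± 0.233 (SD, n = 3) of counts in the control and 4.36% ± 0.661 (SD, n = 12) with wood (exact permutation test over 455 splits, two-sided p = 0.0022, adjusted p = 0.011 over 5 comparisons), lower in 12 of 12 wood libraries. The 100 most abundant held 26.5% ± 0.343 and 17.6% ± 0.999 (exact p = 0.0022). Both tests exchange libraries between the series, although all 3 controls are in the first. Within the first library series the share of the top 10 was 4.69%, 3.85% and 3.55% in the 3 wood libraries, against 7.61% to 8.02% in the controls. Single days and the first series alone cannot pass the threshold, since 3 against 3 gives an exact p of 0.10 at the smallest. Of the 100 most abundant genes over all groups, 33 were lower and 5 higher at day 3, and 33 and 2 at day 11.

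**Figure D3:**
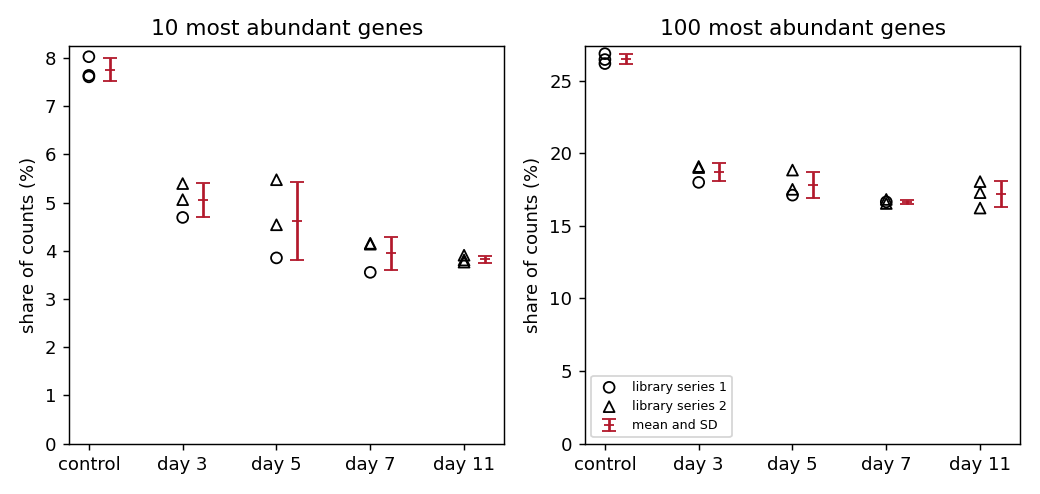
Share of counts (y axis, percent, from 0) held by the 10 and the 100 most abundant genes of each library, by group (x axis, control or days with wood). Symbols are libraries of the first (circles) and second (triangles) series and red bars the mean and SD; the top 10 held 7.76% in the control and 3.83% at day 11.

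The comparisons between wood days ask how expression moved while the wood was present. Few genes passed the test between successive days. From day 3 to day 5, 2 genes were called, both lower. At an unadjusted p under 0.05 there were 904 genes (7.94%) from day 3 to day 5, 533 (4.68%) from day 5 to day 7 and 1238 (10.9%) from day 7 to day 11. One was gene_11960, which fell from 111 ± 23.9 to 45.3 ± 11.3 CPM (SD, n = 3; log2 fold change -1.30, SE 0.15, edgeR adjusted p = 0.028), and stood at 20.7 CPM in the control and 19.9 CPM at day 11. Those 2 means come from different library series. With the series term, its log2 fold change at day 11 against control was -0.59 (edgeR adjusted p = 0.049), short of the 2-fold limit. The other was gene_4338, named here after its values were seen, at 60.0 CPM on day 3. From day 5 to day 7 the only gene called was again gene_4338, which rose from 29.8 ± 6.77 to 66.5 ± 7.81 CPM (SD, n = 3; log2 fold change 1.17, edgeR adjusted p = 0.018), so that day 5 lay below the day on either side. From day 7 to day 11 the only gene called was gene_4914, which rose from 64.6 ± 10.7 to 154 ± 24.6 CPM (SD, n = 3; log2 fold change 1.12, edgeR adjusted p = 0.038), with 258 CPM in the control. With DESeq2 these 3 comparisons gave 61, 26 and 87 genes. With edgeR but without the series term they gave 0 in each, with 599, 361 and 688 genes at an unadjusted p under 0.05. The calls of gene_11960, gene_4338 and gene_4914 were lost in 6, 5 and 12 of the 15 fits that leave out 1 library.

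Day 11 and day 3 differed in 162 genes, 83 higher and 79 lower at day 11. Means followed the order of days 3, 5, 7 and 11 in 44 of the 83 and 61 of the 79. Day 5 lay between days 3 and 11 in 75 and 76 of them, but the genes were chosen for differing between those 2 days. These are means of CPM without a series term, and only day 11 lacks first-series libraries. The number of genes in order by chance was not computed. Against the control, 38 of the 83 were not called at day 3 and higher at day 11, and 12 were lower at day 3 and not called at day 11. Of the 79, 28 went from not called to lower and 23 from higher to not called. The top-ranked riser was gene_1279, from 3.12 ± 2.12 to 26.0 ± 7.63 CPM (SD, n = 3; log2 fold change 3.24, SE 0.67, edgeR adjusted p = 0.027), with 14.9 CPM in the control. The top-ranked falling gene, gene_11931, went from 53.8 ± 81.4 to 0.324 ± 0.193 CPM (SD, n = 3; log2 fold change -7.43, SE 1.28, edgeR adjusted p = 0.015), and without replicate 2 of day 3 the log2 fold change was -3.99. Leaving out 1 library ended the call of gene_1279 in 5 fits and that of gene_11931 in 2, and gene_1279 had an edgeR adjusted p of 0.058 without the series term. The count of 162 was 92 in the second series alone (67 genes shared), 44 without the series term and 336 with DESeq2. It was 48 without replicate 2 of day 3, and 84 and 74 without replicates 1 and 2 of day 11. Over all 4 wood days, 115 genes differed, 21 without the series term, 20 in the second series alone and 1033 with DESeq2. This count was 23 and 52 without replicates 2 and 3 of day 3, 73 without the unnumbered day 5 library, 67 without replicate 2 of day 7, and 52 and 43 without replicates 1 and 2 of day 11. The counts of 162 and 115 were also much lower with a replicate block, fitted without the unnumbered day 5 library. Those counts are listed in the section on how results depend on processing.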

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

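The tests by scaling, by depth and by dealing counts at random were chosen only after the results were seen, while the fits by library series and without single libraries were planned and only the bounds they are held to here were set afterwards. The splits for the mean of the wood days were drawn again as distinct sets of control libraries after a first draw had repeated a set, and that set is given below.

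Effects of wood that differ between time points drew attention in 6 counts. Day 11 and day 3 differed in 162 genes, day 5 and day 3 in 2, day 7 and day 5 in 1, day 11 and day 7 in 1, and the 4 wood days among themselves in 115. The shift between library series differed between days 3, 5 and 7 in 34 genes, beside 876 genes (7.69%) at an unadjusted p under 0.05.

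The first pattern is the difference of wood libraries from controls, 1247 genes for the mean of the wood days. Of 100 drawn splits, out of 455 possible sets of 3 control libraries, only 1, the real one, gave as many genes, and the highest other gave 7. The sets were drawn over both library series, although all 3 controls are in the first. They thus show little of what sets within that series would give. When the 3 wood libraries of the first series were taken as controls, a set not drawn, 1284 genes were called, since inside that series this is the mirror image of the real split. A series effect is argued against by the first series alone, where 1092 genes were called, 980 of them shared. A few genes taking most of the counts would move the others by 1 common factor. As the whole cause this is argued against by the 890 genes called both with TMM factors and with library totals. Of these, 477 were higher and 413 lower (46.4%). They include all 477 genes called higher with TMM factors, so this overlap adds little to the splits given above for each scaling. Age of the cultures cannot be told apart from wood, since 0 libraries without wood were harvested later than the control, and a response to wood stays open beside it. For single days, 6 libraries make 10 splits, too few for a share under 0.05, and 1 split, the real one, was as large each time: 1042, 1138, 1421 and 1213 genes against at most 3, 2, 2 and 1 in the others.

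The second pattern is the difference of day 11 from day 3. The second series alone called 92 genes, which argues against a series effect as the whole cause. Unequal depth is argued against by the totals, 32963058 to 46377457 at day 3 and 40193836 to 43749078 at day 11, which overlap. Thinning all libraries to 1 total left 160 genes, but with such totals it had little difference to remove. Leaving out single libraries took the count below 50% for 2 of them, replicate 2 of day 3 (48) and replicate 2 of day 11 (74), so dependence on a single library stays open. With 10 splits no share under 0.05 is possible: the real value was 162 and the highest other 10. For days 5 and 3, 3 of 10 splits gave as many as the real 2 (highest other 3), for days 7 and 5 it was 5 of 10 (real 1, highest 3) and for days 11 and 7 it was 4 of 10 (real 1, highest 3). Of 100 splits of the 12 wood libraries, only the real one reached 115 genes and the highest other gave 55, while leaving out 1 library of the real split gave 23 to 157. Those splits also moved libraries between the series.

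The third pattern is a set of 154 tested genes that range 100-fold or more between libraries of 1 group, in 298 combinations of gene and group, of which 19 genes were called on at least 1 wood day, gene_1523, gene_2487 and gene_2368 among them. A single contaminated library is argued against by the highest share in any library, 10.1%. The counts of all 11386 tested genes were also dealt out at random over the libraries of each group, as counting noise would do. In 100 draws at most 0 such combinations arose, against the 298 observed. The range rule itself asks for about 325 counts in the highest library, which counting noise alone cannot spread 100-fold over similar libraries. That 0 was therefore fixed by the rule and is no separate evidence against counting noise. Reads shared with a near-identical copy stay open: a gene with a matching loss was found for 97.7% in the gaining library and 97.5% in the others, a difference of 0.168 percentage points, and a measure so near its ceiling decides nothing. No biological explanation was tested.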

How the results depend on the processing

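Alternatives added after seeing the data are thinning, library totals, single libraries of the first series, and fits without abundant or erratic genes. Counts against the control stayed within 1.5 times under DESeq2, other factors, filters and each left-out library; of the named genes' alternatives, 289 kept the call and 74 lost it without a change of sign. Without the series term days 3, 5, 7, 11 and the mean gave 1225, 1188, 1498, 1366 and 1505 genes, sharing 815, 855, 1064, 794 and 920 with the report's fit. With no fold threshold the counts at days 3, 5, 7 and 11 and for the mean were 2605, 2816, 3424, 2587 and 3452, and 473 for day 11 against day 3, by construction. With 1 library of the first series per day they were 375, 325 and 478, with fewer samples. With log2(FPKM + 0.1) days 5, 7, 11 and the mean gave 1789, 2376, 2279 and 2070 and 1002 genes were shared by all 4 days (644 in the report's fit); with library totals these were 1775, 2294, 2223, 1963 and 983. Under these scalings the median of all genes lay at 0.42 to 0.52 in those comparisons, against 0.0021 to 0.028 in the report's fit. The replicate numbers were not taken to pair the samples, since not every same-numbered pair correlated by over 0.1: within 1 series they correlated by 0.066 on average (-0.051 to 0.31), against 0.021 for different numbers. The 3 first-series wood libraries, all replicate 1, correlated by 0.16 to 0.31. The replicate block with the series term gave 701 genes at day 11 (235 higher and 466 lower), 61 for day 11 against day 3, 3 for day 11 against day 7 and 19 among days; in place of the series term the replicate block gave 32, 4 and 12, and 0 for day 7 against day 5. Both block fits also left out the unnumbered day 5 library, without which alone the count among days was 73. The effect of the block was thus not separated from that of leaving out this library. Under the block, again without that library, the list of newly assembled loci turned its direction at day 5 (camera adjusted p = 0.965). For day 5 against 3, 7 against 5, 11 against 7, 11 against 3 and among days, no series term gave 0, 0, 0, 44 and 21, DESeq2 gave 61, 26, 87, 336 and 1033, and the second series alone gave 8, 4, 0, 92 and 20. Leaving out each library in turn gave 0 to 6, 0 to 4, 0 to 3, 48 to 192 and 23 to 157. Among days, the fits without replicates 2 and 3 of day 3 gave 23 and 52, without the unnumbered day 5 library 73, without replicate 2 of day 7 67, and without replicates 1 and 2 of day 11 52 and 43. Day 5 against 3 gave 1 with log2(FPKM + 1) and 1 with library totals. Day 11 against 7 gave 3 with RLE factors, 2 with upper-quartile factors, 8 and 7 with the FPKM pseudocounts of 1 and 0.1, 4 with the CPM filter, 2 with reference genes only, 3 after thinning, 2 with library totals and 3 without erratic genes. The cause was not tested except where named. Thinning to the lowest library total left 160 genes for day 11 against day 3. That loss of depth hardly changed the count, and greater depth was not tested. In simulation at these depths, 42% of 2-fold and 80% of 4-fold changes between these days were recovered.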

Other observations

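The test on loci that do not overlap was chosen after the first result was seen. One hypothesis was that neighbouring newly assembled loci change together with wood. Over 141 pairs within 5000 bases the fold changes correlated by 0.16 (Spearman, across loci, which are not independent; one-sided permutation p = 0.023). Of these pairs, 69 overlap in position and correlated by 0.30, and reads from overlapping loci may be counted for both. The 72 pairs that do not overlap correlated by 0.046 (p = 0.36), so a shared change was not detected apart from overlapping loci, and so few pairs do not exclude one.

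A second hypothesis was that the changes with wood grow from day 3 to day 11. Genes called in the first series alone were read in the second, which shares no library with it. From day 3 to day 11 the 396 higher genes moved up by a median of 0.17 (log2) and the 696 lower genes moved down by a median of 0.129, with 0.0090 for all genes. Both lie between the bounds set beforehand for growth and for no growth, so the test does not decide.

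In the unnumbered day 5 library, newly assembled loci held 1.76% of counts, against 0.437% to 1.06% in the others. Trametes_gibbosa_newGene_286, singled out after its values were seen, held 0.837% there and at most 0.323% elsewhere. It spans scaffold 87 from 1 to 27876 and has 90 transcripts.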
